A study of Mus musculus with 18 samples.

How the data were processed

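Total RNA from 18 samples of wild type mouse embryonic fibroblasts was labelled with Affymetrix whole-transcript kits and measured on Affymetrix expression arrays, 1 sample per array, per the labels' protocols. The deposited values are intensity values on a linear scale, 1 per probe set. Affymetrix Expression Console 1.1 and PLIER 2.0 are the tools named in the submitters' processing notes; the order and settings of their use are not given in the sources used here. The labels say that the fibroblasts came from 2 mice. They describe the growth medium in ways that differ, and the 3 samples of a time are called biological replicates without further detail of the cultures, so the p-values measure the spread between these samples.

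The table held 35556 probe sets. The platform annotation listed 23410 of them, 21789 with 1 gene symbol and 1621 with several, and 12146 were unnamed here. Only probe sets with 1 symbol were used for genes. Of these, 21698 matched the RefSeq table of assembly GRCm38.p6 by gene identifier, which changed 0 symbols; that table was used for names and for which genes neighbour each other. Where several probe sets named 1 gene (999 genes), the one with the highest mean was kept, leaving 19938 genes. Members of the gene lists without a probe set among these genes are not reported here.

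Intensities were taken as log2(value + 16). A fold on this scale understates the change of dim genes. Array quartiles differed by 0.154 log2 at the lower quartile and 0.11 at the upper, above the 0.1 fixed beforehand, so arrays were quantile normalized. All analyses used R 4.3.3 with limma 3.58.1, and figures used matplotlib. Group means over the 6 times were fitted to all 18 arrays, with lmFit and eBayes, so that every time shared 1 estimate of the spread. That fit gave an F test over the times, the contrast of 46 h with 22 h, and the contrast of 34 h with the mean of 22 h and 46 h. A separate fit of a cosine and a sine with a period of 24 h gave each gene's amplitude, which is the log2 distance from the mean level to the peak, and the first fitted peak from 22 h on. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Times run from 22 h to 46 h, 1 cycle of 24 h, so a rhythm cannot be seen to repeat.

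Before the data were examined, 31 gene lists were fixed, and the 28 with at least 5 measured genes were tested. Lists were tested for a shift in the 2 contrasts with camera, with a preset correlation of 0.01 and with an estimated one, and with fry; they were tested for an excess of calls with a one-sided Fisher's exact test. Apart from some genes under the other observations, which were picked after their values were seen (Mir543, Mir381, Mir496a, Mir541, Rian, Meg3 and Gstm7), the genes named were chosen by a rule fixed at the same time: all measured core clock genes, the 20 called genes with the largest cosine amplitude, the 10 with the largest range, the 8 largest rises and 8 largest falls of each contrast, and up to 4 called members of each list with the smallest p. Gene models without a full name, and olfactory and vomeronasal receptors, were passed over.

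The fits were tested on simulated data drawn with the real means and residual spreads, in 19938 genes of which 200 were changed, 50 at each size. For the cosine test, 58% of genes with an amplitude of 0.15 and 96% of those with 0.25 were called. For the change between 22 h and 46 h, 38% of genes with a change of 0.25 and 88% with 0.5 were called, and for the 34 h contrast 62% and 94%. The F test called 88% of genes with 1 time changed by 0.5. Unchanged genes made up 5 of 182 cosine calls, 11 of 142 calls for 34 h (7.75%), 3 of 120 for 46 h and 0 of 103 for the F test. A list of 19 genes shifted by 0.3 was the 1 list of 28 that passed camera. Simulated genes varied independently of each other, while 33.8% of the variance within times in the real arrays lay along 1 component. They also held no differences between times beyond the change put in. In real genes such differences enter the residual of the cosine, so the shares called by the cosine test may be too high. The shares above thus do not describe the real arrays in full.

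Alternatives covered the normalization, the constant added before the log, filters on dim genes, all probe sets, the replicate number as a block, array weights, variance models, thresholds, other periods, a linear term in time, and each array left out in turn. No column of the table was left unused.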

Results

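Gene expression was measured in wild type mouse embryonic fibroblasts, the connective tissue cells grown out of embryos taken at embryonic day 13, after a 2 h exposure to 100 nM dexamethasone. Dexamethasone is a synthetic glucocorticoid that sets the circadian clocks of cells in a dish to a common phase. RNA was taken at 22, 26, 30, 34, 40 and 46 h, with 3 samples at each time that the labels call biological replicates, and each sample was put on 1 expression array, giving 18 arrays. The median intensity of an array lay between 196 and 210, and the number of arrays limits the precision of every value below. After quantile normalization, 19938 genes were tested on the log2(intensity + 16) scale.

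The first question was which transcripts followed a 24 h cycle. Among the genes that passed the test, the 4 largest cosine amplitudes belonged to genes of the circadian clock. Per3, a member of the period family of clock repressors (probe set 10518781), had an amplitude of 0.79 ± 0.10 (SE, n = 18 arrays) log2 with a fitted peak at 26.9 h (adjusted p = 0.00424, limma), and its mean level was 8.71 ± 0.27 (SD, n = 3) at 26 h and 7.22 ± 0.20 at 40 h. Nr1d1, which encodes the nuclear receptor REV-ERB alpha (probe set 10390691), had an amplitude of 0.64 ± 0.08 and a fitted peak at 44.2 h. On a 24 h cycle that point falls shortly before 22 h, and so ahead of the peak of Per3. The level of Nr1d1 was 10.45 ± 0.23 at 22 h, 9.08 ± 0.15 at 34 h and 10.10 ± 0.18 at 46 h. Dbp, a transcription factor driven directly by the clock, had an amplitude of 0.60 ± 0.09 and a peak at 25.9 h. Per3 and Dbp did not return to their 22 h levels at 46 h. The arrays of Per3 lay from 8.5 to 8.7 at 22 h and from 7.7 to 8.0 at 46 h. Those of Dbp lay from 9.9 to 10.2 and from 9.2 to 9.5.

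Of the 23 genes on the core clock list, 20 were measured, and 9 of these passed the cosine test over all genes (12 adjusted over the list alone). Besides Per3, Nr1d1 and Dbp these were Nr1d2 (amplitude 0.47, peak 23.6 h), Tef (0.41, 26.1 h), Per2 (0.37, 27.2 h), Cry2 (0.31, 27.6 h), Cry1 (0.28, 30.2 h) and Bhlhe41 (0.19, 28.2 h). The list held more such genes than the rest of the array (one-sided Fisher's exact test, adjusted p = 6.36e-13). So did the list of clock genes driven through E-box and D-box elements, where 7 of 10 passed, but all 10 are also on the core clock list. Fisher's test takes genes as independent, while the estimated correlation between genes was 0.10 in the core clock list and 0.43 in the other. Arntl, which encodes the clock activator BMAL1, did not pass (amplitude 0.24 ± 0.07, peak 36.6 h, adjusted p = 0.137), nor did Nfil3 (amplitude 0.15, adjusted p = 0.0665), Bhlhe40 (0.24, adjusted p = 0.146), Ciart (0.27, adjusted p = 0.392) or Per1 (0.07, adjusted p = 0.546). Clock, Csnk1d, Csnk1e, Hlf, Rora and Rorb had amplitudes of at most 0.06. The call for Nr1d2 was lost without any 1 of 8 arrays (replicates 1 and 3 at 26 h, 2 at 30 h, 1, 2 and 3 at 34 h, and 1 and 3 at 40 h), with adjusted p from 0.0525 to 0.0886. Without replicate 3 at 40 h Dbp and Bhlhe41 were lost too (adjusted p = 0.0513 for each), and 6 core clock genes passed. The count of 9 depended on the period fitted: it was 1 at 20 h, 2 at 22 h, 12 at 26 h and 13 at 28 h. It was 8 with a linear term in time and 0 on ranks by limma. No gene on the arrays passed on ranks, although 4639 had an unadjusted p under 0.05, against 4248 on the log2 values. Ranks give every gene the same total spread, which limits how small p can be, so no conclusion is drawn from that 0. When the 6 times were put in other orders, a test chosen after the counts were seen, with the arrays of a time kept together, 20 of 100 orders gave 9 core clock genes or more, the real one included, and up to 14. The other orders with 9 genes or more all put 22 h and 46 h at different points of the cycle, and so hold the difference between these times. Orders drawn that kept both at 1 point gave at most 8 core clock genes, the real one aside, but were too few for a share under 0.05. The count alone therefore does not set a 24 h cycle apart from other differences between times.

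**Figure D1:**
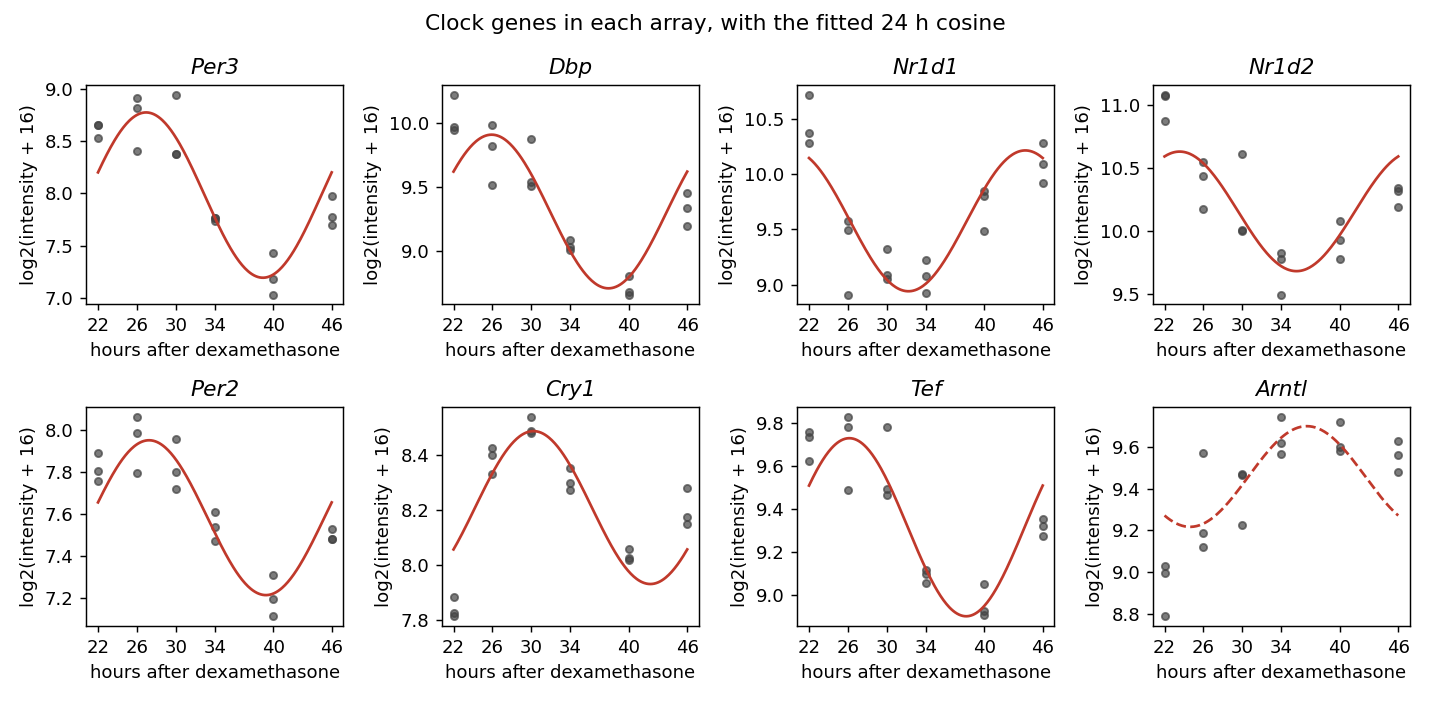
Level of 8 clock genes, log2(intensity + 16), against hours after dexamethasone; each point is 1 array and each line the fitted 24 h cosine, dashed for Arntl, which did not pass the test. Per3 had a mean of 8.71 at 26 h and 7.22 at 40 h, while Nr1d1 was lowest at 34 h, at 9.08.

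Over all genes, 165 passed the cosine test, with amplitudes from 0.10 to 0.79 and a median of 0.17 log2. Fitted peaks lay from 26 to 30 h for 79 genes, from 30 to 34 h for 31 and from 38 to 42 h for 43. Outside the clock, the largest amplitudes among these genes belonged to the small nucleolar RNA Snord118 (0.44 ± 0.09, peak 27.7 h), Adamtsl3 (0.34 ± 0.06, 27.6 h), Cyp2f2 (0.33 ± 0.06, 29.4 h) and Snora75 (0.30 ± 0.06). Smaller amplitudes included those of Avil (0.28), Acss2, an acetyl-CoA synthetase (0.25 ± 0.03, 29.5 h), Dqx1 (0.25) and the prostaglandin receptor gene Ptgfr (0.24). The microRNA genes Mir376c (0.28) and Mir154 (0.26) peaked at 26.1 h and 27.2 h. Later peaks were those of Hacd1 (0.26, 40.8 h), Ccn1, a matrix-associated target of YAP signalling (0.26, 42.1 h), the smooth muscle actin gene Actg2 (0.21) and the cardiac actin gene Actc1 (0.22, 39.3 h). The calls peaking from 38 to 42 h had a median level of 7.88 log2, between the median (7.11) and the 90th percentile (8.21) of 66 marker genes of other cell types. The count was not stable. On ranks by limma it was 0 (4639 at an unadjusted p under 0.05), from which no conclusion is drawn, as for the core clock. It was 1 and 5 at periods of 20 and 22 h, and 1985 and 3909 at 26 and 28 h. Without the arrays of 22 h it was 2235, and without those of 46 h 2159. A 24 h cosine gives 22 h and 46 h the same fitted level. Other periods and fits without either time lift that limit, so their counts can hold the difference between these times. With single arrays left out the count of 165 ranged from 22 without replicate 3 at 40 h to 298 without replicate 2 at 40 h. With a linear term in time it was 34, of which 28 were among the 165. With the array values as deposited it was 541. Of the same 100 orders of the times, 36 gave 165 genes or more, the real one included, and up to 5116. The others among these all put 22 h and 46 h at different points of the cycle. Orders that kept both at 1 point gave at most 140 genes, the real one aside, but were too few for a share under 0.05.

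**Figure D2:**
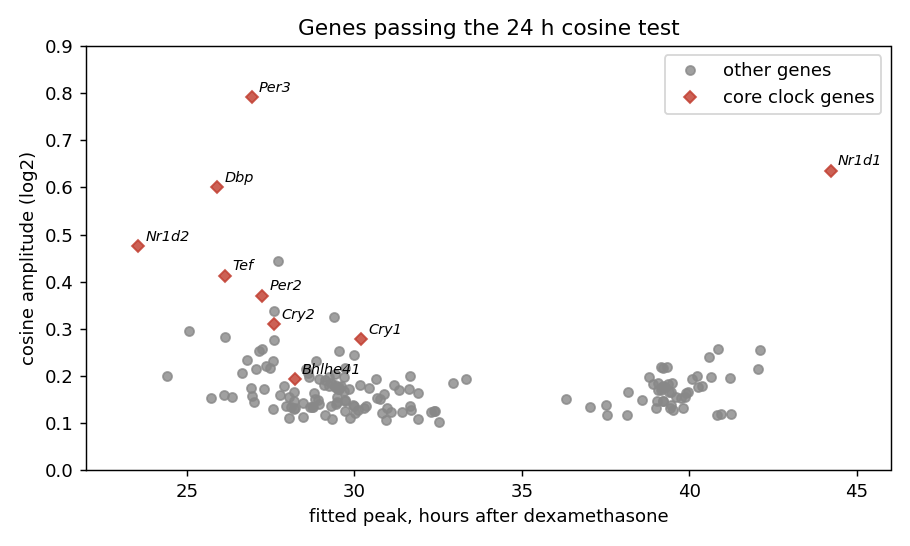
Cosine amplitude (log2) against fitted peak time (hours after dexamethasone) for the 165 genes that passed the 24 h cosine test; each point is 1 gene and diamonds mark the 9 core clock genes. Of the 165 genes, 79 peaked from 26 to 30 h and 43 from 38 to 42 h. The axis spans 1 cycle, so its ends meet, and the peak of Nr1d1 at 44.2 h lies shortly before those at the left edge.

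The second question was which genes changed over the 6 times in any manner. The F test called 3957 genes, with a median range of 0.33 log2 between the highest and lowest time mean. The largest ranges belonged to the spliceosomal RNA gene Rnu5g (2.19) and the acute-phase gene Serpina3n (2.02), followed by the mitotic genes Aspm (1.91), Hmmr (1.90), Cenpe (1.85), Kif2c (1.81), Kif4 (1.81), Cenpf (1.80) and Cdkn3 (1.78), and by Pi15 (1.80), a secreted protease inhibitor. All but Rnu5g and Serpina3n had their extremes at 22 h and 46 h. Among the called genes, 1234 were highest and 1432 lowest at 22 h, and 994 were highest and 1215 lowest at 46 h. The core clock passed in 16 of 20 genes, including Arntl, whose mean level was 8.94 ± 0.13 at 22 h, its lowest, and 9.64 ± 0.09 at 34 h, its highest (adjusted p = 0.000498, limma's F test). Without replicate 3 at 22 h the F test called 2631 genes, and with the values as deposited 6595.

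The third question was which genes differed between 22 h and 46 h, which are 24 h apart. Genes of cell division were lower at 46 h. All 29 measured genes of the G2/M and mitosis list fell, by a median of -1.55 log2, including Hmmr (-1.90 ± 0.09, SE), Cenpe (-1.85 ± 0.11) and Cenpf (-1.80 ± 0.11), which act in spindle assembly and chromosome segregation. Aurka, Prc1, Tpx2 and Kif20a of the list fell by 1.47, 1.72, 1.54 and 1.61. Over all genes, the 8 largest falls also took in genes outside that list: the mitotic genes Aspm (-1.91 ± 0.08), Kif2c (-1.81 ± 0.09) and Kif4 (-1.81 ± 0.10), along with Serpina3n (-1.88 ± 0.22) and Rnu5g (-1.84 ± 0.27). The median of the list relative to 22 h was -0.64 ± 0.10 (SD, n = 3 arrays) at 26 h, -0.82 ± 0.07 at 34 h and -1.54 ± 0.10 at 46 h. Of 31 measured genes of the G1/S and DNA replication list, 28 fell, by a list median of -0.70, among them Exo1 (-1.11), Uhrf1 (-1.11), Mcm5 (-0.96) and Mcm3 (-0.82). The G2/M list passed camera's test against other genes (adjusted p = 8.22e-57) and passed with an estimated correlation (adjusted p = 0.0193), whereas the G1/S list did not pass then (adjusted p = 0.0536 with an estimated correlation).

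Lipid synthesis genes were also lower at 46 h. Of 19 measured cholesterol synthesis genes 18 fell, with a list median of -0.68, including Insig1 (-0.93 ± 0.06), Fdft1 (-0.86 ± 0.06), Lss (-0.81 ± 0.06) and Hmgcs1 (-0.68 ± 0.06). This list passed with an estimated correlation (adjusted p = 0.0101). Of 11 fatty acid synthesis genes 8 fell, including Acaca (-0.42), Elovl6 (-0.42), Me1 (-0.40) and Scd1 (-0.34) (adjusted p = 0.0536 with an estimated correlation). Of 20 glycolysis and hypoxia genes 13 fell, such as Pgk1 (-0.59), Slc2a1 (-0.40) and Pgam1 (-0.33), and 2 rose, including Adm (0.80), which encodes the vasodilator peptide adrenomedullin (adjusted p = 0.0726 with an estimated correlation).

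Genes of the extracellular matrix were higher at 46 h. Of 25 measured genes of that list 18 rose and 2 fell, with a list median of 0.34, and the largest rises included Postn (1.65 ± 0.10), Thbs2 (1.48 ± 0.10), Lum (1.29 ± 0.11) and Col6a3 (0.73 ± 0.06). The list passed camera (adjusted p = 6.40e-10) but not with an estimated correlation (adjusted p = 0.0536). Over all genes the largest rises were those of Pi15 (1.80 ± 0.13), Sema3c (1.72 ± 0.14), Postn, the growth factor gene Igf1 (1.65 ± 0.09), Thbs2, Fbln7 (1.39 ± 0.11), Aspn (1.36 ± 0.17) and Mylk (1.35 ± 0.08). Of 18 unfolded protein response genes 10 rose, including Xbp1 (0.31), Sdf2l1 (0.32) and Hspa5 (0.32), and 1, Asns, fell (-0.43) (adjusted p = 0.116 with an estimated correlation). The list passed camera (adjusted p = 0.00468), but not with the values as deposited (adjusted p = 0.0918).

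**Figure D3:**
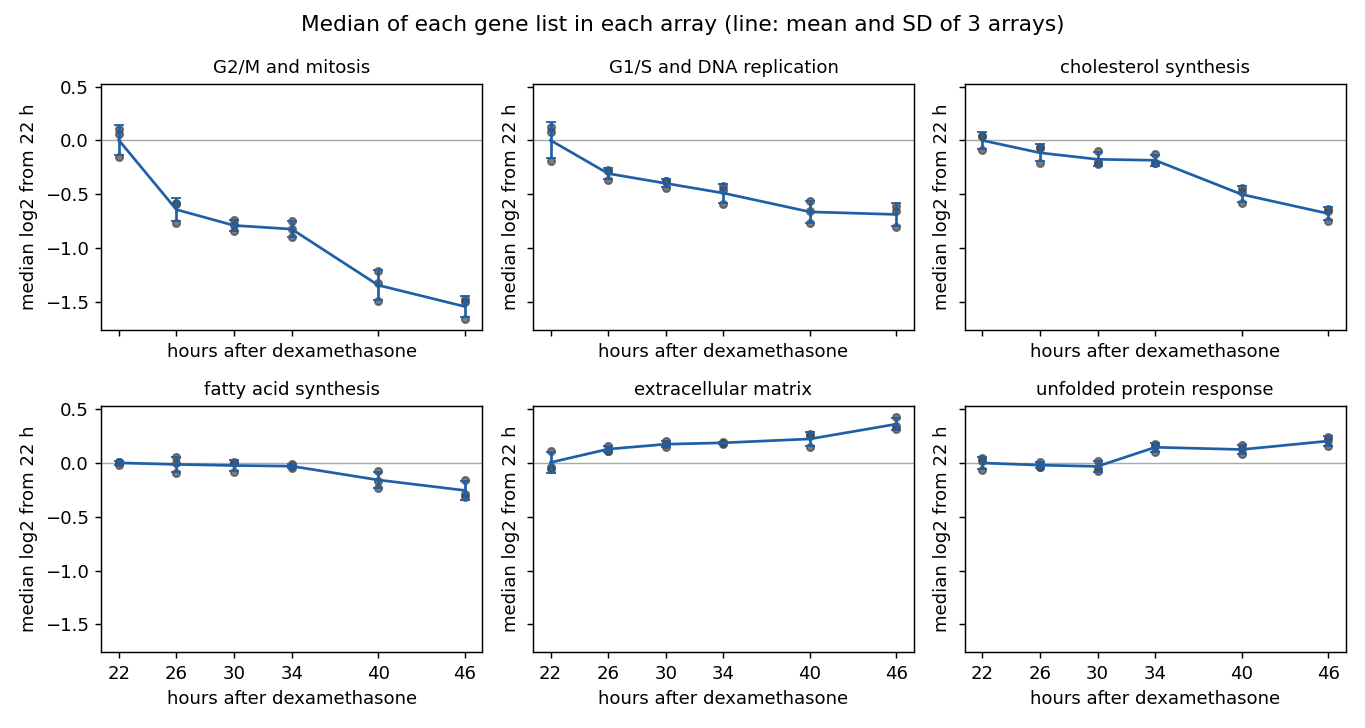
Median log2 change from 22 h over the genes of 6 lists, against hours after dexamethasone; points are arrays, and lines with bars the mean and SD of 3 arrays. The G2/M list reached -1.54 and the cholesterol list -0.68 at 46 h, while the extracellular matrix list reached 0.36.

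Of 15 inflammatory genes 6 fell, including the chemokine genes Ccl7 (-0.68) and Ccl2 (-0.41), with Lif (-0.36) and Tnfaip3 (-0.33) (adjusted p = 0.0536 with an estimated correlation). Of 13 YAP and TGF-beta target genes 7 fell, such as Tgfbi (-0.55), Ltbp2 (-0.53) and Id2 (-0.47), and 2 rose, including Ccn1 (0.39) (adjusted p = 0.116 with an estimated correlation). Of 11 NRF2 targets 4 fell, among them Nqo1 (-0.93) and Slc7a11 (-0.56), and 1, Gsta4, rose (0.33) (adjusted p = 0.116 with an estimated correlation). Within the E-box and D-box arm of the clock 6 of 10 genes fell, Ciart the most (-1.24 ± 0.15), and 2 rose (adjusted p = 0.286 with an estimated correlation). Of 18 glucocorticoid-induced genes 7 rose, including Dusp1 (0.73), Hif3a (0.64) and Klf9 (0.32), and 1 fell; that list did not pass camera (adjusted p = 0.0542). Of 19 immediate early genes 6 fell, including Myc (-0.88) and Klf4 (-0.68), and 4 rose, including Btg2 (0.49) and Fos (0.33). Of 12 fibroblast markers 5 rose, including Lum, Pdgfra (0.45) and Col1a1 (0.41), and 2 fell, and the list did not pass camera (adjusted p = 0.124). None of the other marker lists that were tested, for adipocytes, skeletal muscle, bone and cartilage, macrophages, endothelium, epithelium and neural cells, passed camera, although the keratin gene Krt19 of the epithelium list fell by 0.93. The same held for the core clock, clock output, immediate early, heat shock, interferon, p53 and ribosomal protein lists. Smooth muscle genes did not pass camera either (adjusted p = 0.0693), and 5 of 14 rose, including Myl9 (0.72). Camera was used for a shift of a list in 1 direction, and the core clock list moved in both. Of its 20 measured genes 14 were called, 6 higher and 8 lower at 46 h, while 21.2% of all genes were called.

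In all, 4234 genes differed between 22 h and 46 h by limma's test, 2295 of them higher and 1939 lower at 46 h. Of these, 19 rose and 156 fell by at least 2-fold. Of the 28 gene lists tested, 11 passed camera with its preset correlation, and of these the G2/M and cholesterol lists also passed with an estimated one. With the values as deposited 3863 genes were higher and 2180 lower, so 63.9% of the calls were rises instead of 54.2%. Without replicate 1 at 22 h the count was 2789, with 1351 genes higher and 1438 lower, and without replicate 2 at 46 h 1471 were higher and 1577 lower, so single arrays turned the balance of rises and falls. Without replicate 3 at 22 h 1481 were higher and 1387 lower.

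The last comparison set 34 h against the mean of 22 h and 46 h, which lie 12 h to either side. Clock genes stood out among those lower at 34 h: Nr1d1 by -1.20 ± 0.14 log2, Nr1d2 by -0.95 ± 0.12, Dbp by -0.65 ± 0.10 and Tef by -0.42 ± 0.08. Also lower were Rnu5g (-1.24 ± 0.23), the immediate early gene Nr4a1 (-0.37), Ccn2, a YAP target (-0.34), and Npnt (-0.20). Higher at 34 h were the glutathione transferase genes Gstt1 (0.42 ± 0.06), Gstm1 (0.38 ± 0.07) and Gstm3 (0.29 ± 0.05), along with Lrrc17 (0.40), Tgfbi (0.36), Lbp (0.33), P2rx6 (0.33), Slc16a4 (0.32) and the clock repressor gene Cry1 (0.29 ± 0.04). The list of E-box and D-box clock genes was lower by camera (adjusted p = 1.64e-12), and that call was lost with an estimated correlation (adjusted p = 0.0766). The other 10 lists past camera's threshold in this comparison were also lost with an estimated correlation, with adjusted p from 0.0766 to 0.657. Against the mean of 22 h and 46 h, the core clock, G1/S, G2/M, immediate early, smooth muscle, YAP and TGF-beta, and glycolysis lists were lower at 34 h. The cholesterol, fatty acid and interferon lists were higher than that mean. Relative to 22 h, the median of the G2/M list was -0.82 at 34 h and -1.54 at 46 h, and that of the G1/S list -0.49 and -0.69. The cholesterol list stood at -0.185 and -0.68, and the fatty acid list at -0.03 and -0.26. At 34 h these lists thus lay between their levels at 22 h and 46 h, not at a high or low point.

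This contrast called 27 genes in all, 19 higher and 8 lower at 34 h. Arrays with negative values on the largest component of the variance within times made up 2 of 3 at 22 h and at 46 h, and 1 of 3 at 34 h. Values of this component sum to 0 within each time, so that split cannot show whether a batch differed between times. The count moved with single arrays, to 2 without replicate 2 at 34 h, 0 higher and 2 lower, and 138 without replicate 2 at 22 h. With only the arrays of 22, 34 and 46 h, 0 genes were higher and 4 lower by limma's test. Assignments of the arrays of 22, 34 and 46 h to these times reached 27 genes or more in 7 of 100 cases, the real one included. The 6 others each put 2 or 3 arrays of 22 h, or 3 of 46 h, in the place of 34 h, and so hold the difference between these times. The regroupings therefore do not settle whether chance is excluded. With the values as deposited 16 genes passed, 6 higher and 10 lower, and with each probe set tested on its own 8 were higher and 20 lower.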

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

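The fits with array set as a block, alone or together with a linear term, were chosen after seeing the data. All other settings here were fixed before. The array sets were read from the first component of the residuals from the time means. They were thus chosen for the spread that the block takes out, and its larger counts are not independent support. The sets are unbalanced along the 34 h contrast, and residuals cannot show a set effect that the time means took up. Fits within each set of arrays were also run and are not reported, because the sets come from the measured values.

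The cosine count of 165 was 541 as deposited, 277 without the lowest 25% of genes by mean level, 32 with the replicate block, 1140 with array weights, 9 at a threshold of 0.01 and 19 with a minimum amplitude of 0.25. It was 34 with a linear term, 1, 5, 1985 and 3909 at periods of 20, 22, 26 and 28 h, 2496 against the spread within times, 0 on ranks (limma; 4639 at an unadjusted p under 0.05), 2235 without 22 h, 2159 without 46 h and 641 with array set as a block. The core clock count of 9 was 1, 2, 12 and 13 at periods of 20, 22, 26 and 28 h, and ranged from 6 to 10 with single arrays left out. The F test count of 3957 was 6595 as deposited, 10765 with array weights, 1845 at 0.01, 777 with a minimum range of 0.5 and 6326 with array set as a block. The count for 46 h against 22 h, 4234, was 8790 with array weights, 2391 at 0.01 and 670 with a minimum change of 0.5. The count for 34 h, 27, was 16 as deposited, 66 with log2(value + 64), 72 and 107 without the lowest 25% and 50%, 7 with the replicate block, 59 with a mean-variance trend, 952 with array weights, 4 at 0.01, 4 with a minimum change of 0.5, 4 with only the arrays compared and 107 with array set as a block. The causes were not tested, except that higher thresholds and minimum sizes can only lower a count.

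Leaving out single arrays gave 22 to 298 genes for the cosine test, 2 to 138 for 34 h, 2631 to 4685 for the F test and 2789 to 4741 for 46 h against 22 h. The cosine count was 263 without replicate 1 at 22 h, 70, 51 and 42 without replicates 1, 2 and 3 at 26 h, 48 and 59 without 2 and 3 at 30 h, 99, 81 and 84 without 1, 2 and 3 at 34 h, 75, 298 and 22 without 1, 2 and 3 at 40 h, and 83 without 1 at 46 h. The 34 h count was 6, 138 and 6 without 1, 2 and 3 at 22 h, 8 and 6 without 1 and 3 at 26 h, 6 without 1 at 30 h, 9, 2 and 6 without 1, 2 and 3 at 34 h, and 7, 15 and 7 without 1, 2 and 3 at 46 h. The lowest F test count was without replicate 3 at 22 h, and the lowest for 46 h against 22 h without replicate 1 at 22 h. Lists past camera's threshold numbered 11 for 34 h, 0 with an estimated correlation (7 at an unadjusted p under 0.05) and 5 by fry, and 11 for 46 h against 22 h, with 2 by an estimated correlation and 16 by fry. The fatty acid list at 34 h lost its call with the replicate block (adjusted p = 0.0564), the G2/M list at 34 h with array set as a block (adjusted p = 0.219), and the unfolded protein response list at 46 h as deposited (adjusted p = 0.0918). Named genes were refitted as deposited, with log2(value + 1) and log2(value + 64), with both blocks, with a linear term and without each array. None changed its sign or, if called rhythmic, its peak by over 6 h; 161 such values for 34 h, 176 for the cosine, 74 for 46 h against 22 h and 59 for the F test lost their call. Nr1d2 lost its cosine call with the replicate block (adjusted p = 0.0675) and Bhlhe41 with a linear term (adjusted p = 0.0541).

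Replicate numbers did not pair the samples. Arrays with the same number at different times had a median correlation of deviations of -0.0982, with 15 of 45 pairs over 0.1, and 6 of 18 arrays correlated best with their own number. With the replicate block the F test called 3220 genes, the 46 h contrast 3838 and the core clock 8.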

Other observations

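The counts from regrouping single arrays were planned; the other tests in this part were chosen after the results were seen. Several microRNAs of the imprinted Dlk1-Dio3 region of chromosome 12 (neighbours by assembly GRCm38.p6) passed the cosine test. Of 40 measured there, 30 had a fitted peak from 24 to 30 h and 6 passed the cosine test: Mir543, Mir376c, Mir381, Mir154, Mir496a and Mir541, with peaks from 26.1 to 27.6 h. The share of other genes with a peak from 24 to 30 h was not taken, so the 30 show no excess by themselves. Among the long noncoding RNAs of the region, Rian had an amplitude of 0.11 (adjusted p = 0.312) and Meg3 one of 0.02 (adjusted p = 0.923), neither passing the test. Of 247 microRNAs elsewhere, 3 passed. The region was picked because of its calls, so the difference in share was not tested.

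Of 53 small nucleolar RNA genes, 27 were lower at 46 h than at 22 h and 0 higher (median -0.28, and -0.27 as deposited). Of 19 glutathione transferase genes, 4 were higher at 34 h (Gstt1, Gstm1, Gstm3 and Gstm7), and 17 had a positive difference (median 0.15, and 0.13 as deposited); 3 passed as deposited, and 0 passed without replicate 2 at 34 h or with only the arrays of 22, 34 and 46 h. Both families were picked after their values were seen, so no test of their excess is given.

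The calls among microRNAs of the region could come from a drift in time that the cosine had taken up. Adding a linear term would then shrink their amplitudes, and the median ratio was 0.966 for the 6 called genes. That argues against a straight-line drift as the whole of it. Calls by a cosine that gives 22 h and 46 h the same fitted level favour such a ratio, and drift of other shapes was not tested. With that term 2 of the 6 passed; the standard errors had a median ratio of 1.14, and what ended the other calls was not separated. A property of microRNA probe sets in general would also show outside the region. There 3 of 247 microRNAs passed, so calls were few among microRNA probe sets elsewhere. The region was picked because of its calls, so its larger share, 6 of 40, cannot decide the question, and no conclusion is drawn. No biological explanation was tested.

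The 43 cosine calls peaking from 38 to 42 h could be dim probe sets near background. Their median level was 7.88 log2, against 7.88 for calls peaking from 26 to 30 h. It lay between the median, 7.11, and the 90th percentile, 8.21, of 66 marker genes of other cell types, so near-background signal stays open for both. Over all 165 calls, adding a linear term changed amplitudes by a median ratio of 0.87, with a median ratio of 1.05 for the standard errors, and 28 of these genes still passed. A straight-line drift thus does not account for most of the amplitude of these calls, and what ended the other calls was not separated. The 24 h cosine gives 22 h and 46 h the same fitted level, which favours calls with such ratios. Of the 165 calls, 136 were not called between 22 h and 46 h. Drift of other shapes was not tested.

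The lower level of G2/M genes at 46 h could come from the quantile normalization, but the list median was -1.58 as deposited. It could also rest on 1 array, but with each array of 22 h and 46 h left out the median nearest 0 was -1.49. Both argue against those explanations. Other processes that run with time in culture stay open and untested, since the design gives no way to separate them.

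Regrouping the arrays bears on chance. Of 100 assignments of the 18 arrays to times, 1, the real one, reached 3957 genes in the F test (highest other 5). Chance assignment of single arrays is thus excluded as the source of a difference between times. The labels give no detail of the cultures, so variation shared by the 3 samples of a time is not covered. In the cosine test 1 reached 165 genes (highest other 3) and 1 reached 9 core clock genes (highest other 0). Mixing arrays of different times moves the differences between times into the residual of the cosine, so these low counts bear on a difference between times and not on a 24 h cycle. Orders of the 6 times with the arrays of a time kept together change only the place of each time in the cycle. Of 100 such orders, 36 reached 165 genes (highest other 5116) and 20 reached 9 core clock genes (highest other 14), the real one included in each, so differences between times in an order that is not a 24 h cycle are not excluded as the source of either count. Many of these orders put 22 h and 46 h at different points of the cycle and so hold the difference of 4234 genes between them. In the 11 other orders drawn that kept both at 1 point the highest counts were 140 genes and 8 core clock genes, and 12 orders are too few for a share under 0.05. Not all orders of that kind were drawn. For 34 h, 7 of 100 assignments of the arrays of 22, 34 and 46 h reached 27 genes and the highest other gave 3506. The 6 others that reached it put 3 arrays of 22 h (3506 and 3420 genes), 3 of 46 h (1713) or 2 of 22 h with 1 of 34 h (1280, 488 and 34) in the place of 34 h. Since 22 h and 46 h differ in 4234 genes, these assignments hold a difference between times, and the regroupings do not settle whether chance is excluded for 34 h. For 46 h against 22 h, 1 of the 10 possible splits reached 4234 genes (highest other 0), and 10 splits are too few for a share under 0.05.

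The arrays held a structure that the labels do not name. A single component took 33.8% of the variance within times. Its values ran from -0.406 for replicate 2 at 40 h to 0.426 for replicate 2 at 22 h, with 8 arrays below 0 and 10 above. Of the 3 arrays of a time, 2 were below 0 at 22 h and at 46 h and 1 at each other time. The component came from deviations from the time means, so its values sum to 0 at each time. Each time therefore had to hold arrays on both sides, and the split cannot show whether a batch differed between times.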
